A study of Mus musculus with 16 samples.

How the data were processed

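The samples were mouse prostate organoids, 3-dimensional cultures of prostate epithelium, and the assay was sequencing of polyadenylated RNA. Per the labels, the organoids were either Control or SPOP-mutant (SPOPmut below), and carried either a CRISPR guide against exon 2 of the androgen receptor gene (sgAR) or a control guide (sgNT). SPOP is the substrate-binding part of a ubiquitin ligase that is mutated in a share of prostate cancers; which mutation the organoids carried is not stated in the labels used here. Per the labels' protocols, all organoids had 10 nM dihydrotestosterone (DHT), the most potent natural androgen, for 24 h in a medium lacking mEGF, so the design holds no arm without androgen. RNA was purified with DNase treatment and made into stranded libraries after poly-A selection, per the labels' protocols.

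The authors deposited a table of read counts per gene, with 35999 gene symbols and a column for 14 of the 16 labelled samples. Per the submitters' processing notes, reads were aligned with Bowtie2 2.3.4.1 to mm10; the program that counted the reads, its gene annotation and whether it used the strand are not given in the sources used here. The values were checked to be whole numbers, and the spread between replicates was above counting noise, with a chi-square per degree of freedom from 11.79 to 128.02. The 2 samples without a column were sgNT Control replicates 1 and 4, which the labels mark as left out of the final analysis, so that group had 2 libraries and each of the other 3 groups had 4. In 26 symbols a spreadsheet had turned the gene name into a date; these held 0.137% of all counts and were kept as they stood. Of the symbols, 12050 had no count in any library.

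All 14 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, with a mean per group, TMM scaling, quasi-likelihood F-tests (2-sided) and 10 residual degrees of freedom. Genes were kept by edgeR's filterByExpr on the groups (minimum count 10, minimum total 15), which left 14204 genes tested. P values were adjusted by the Benjamini-Hochberg method over these genes within each comparison, and a gene was called at an adjusted p below 0.05. The 5 comparisons were AR targeting in Control organoids, AR targeting in SPOPmut organoids, SPOP mutation with sgNT, SPOP mutation with sgAR, and the difference between the SPOP effects with the 2 guides (an interaction, which equals the difference between the AR-targeting effects in the 2 genotypes). Fold changes are fitted log2 values with standard errors (SE). Levels are counts per 1000000 (CPM) on TMM-scaled library sizes, given as mean ± SD over a group's libraries: n = 2 for sgNT Control and n = 4 for each other group, unless stated. Where no library of a compared group held over 6 counts of a gene, levels and counts are given instead of a fitted fold change, apart from a list of fitted interactions.

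Gene lists were written from textbook knowledge before the data were examined, as were the comparisons, the tests, most alternatives and the rule for naming genes. Of 30 lists, 28 had at least 3 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. No list call held when the correlation was estimated from the residuals of each list; that p is given beside each call. Each count of called members is given over all genes tested and adjusted over the list alone. The rule named Ar, Spop, Nkx3-1, Fkbp5, Pbsn and Tmprss2 in every comparison; the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM and no overlap between the CPM of the compared groups (overlap was not considered for the interaction); and up to 3 called members of each list. The text prints a part of the genes the rule named. Any gene outside the rule is said to be so.

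Whether replicate numbers pair samples across groups was checked from residual correlations. Libraries of the same number correlated in every pair between sgAR Control and sgAR SPOPmut (0.19 to 0.45), between sgNT SPOPmut and sgAR SPOPmut (0.12 to 0.34) and between sgAR Control and sgNT SPOPmut (0.24 to 0.37), with medians of -0.12, -0.06 and -0.19 for unlike numbers. For sgNT Control only 2 pairs exist: they gave 0.20 with sgAR Control and -0.06 to 0.06 with sgNT SPOPmut, too few or too low to treat as pairs. Values with the replicate number as a block are given beside results of the paired comparisons where they change a call or move a count over 1.5 times.

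The steps were tested on simulated counts drawn from the real means and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. At 2-fold and 4-fold, the tests recovered 46% and 87% for AR targeting in Control organoids (13911 genes), 50% and 84% in SPOPmut organoids (13944 genes), 44% and 79% for SPOP mutation with sgNT (13945 genes), 60% and 79% with sgAR (13928 genes), and 24% and 72% for the interaction (13937 genes). Wrong calls numbered 5, 3, 6, 8 and 2 in the same order. Camera called the shifted list and 1 of 100 unshifted lists at the 0.05 level. The simulated genes varied independently of each other, so this rate does not cover real lists whose genes vary together.

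Library totals ran from 15748814 to 22403800 counts. A count of 0 in the smallest library allows a level of up to 0.19 CPM (3 counts); such limits cover counting error only. Positions are those of the GENCODE annotation of mm10, 1-based. Apobr, Arhgdib, Cebpd, Cp, Fdft1, Gata3, Glul, Masp1 and Ncoa3 overlap another gene on the opposite strand, Tmc4 and Gata3 overlap another on the same strand, and Pcdhgc3 shares sequence with the other gamma protocadherins, so reads of neighbours could be included in their counts. Alternatives tried were DESeq2 1.42.0 size factors in place of TMM, no filter, the DESeq2 Wald test, limma-voom with quality weights, only the groups compared, a minimum absolute log2 fold change of 1, the replicate block, and leaving out each library in turn. After the data were seen, removal of each chromosome's median shift per library and a fit without the 3 libraries of replicate number 1, which had the lowest Gapdh, were added. Lists were also tested with fry. Figures were drawn with matplotlib 3.10.9.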

Results

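Transcript levels were measured in 14 libraries of mouse prostate organoids, all exposed to the androgen DHT for 24 h. They formed 4 groups: sgNT Control (2 libraries), sgAR Control (4), sgNT SPOPmut (4) and sgAR SPOPmut (4). The labels do not say how many organoid lines or mice stand behind a group. The tests therefore measure spread between libraries, which need not be spread between lines. A difference between lines can enter any comparison named below for the guide or the mutation. Total counts ran from 17269743 to 18441496 in sgNT Control, from 16242951 to 19226406 in sgAR Control, from 15748814 to 22403800 in sgNT SPOPmut and from 16517208 to 19388079 in sgAR SPOPmut. The 4 groups separated on a principal component analysis of 1000 variable genes, whose first 3 components held 32.9%, 18.2% and 12.9% of the variance. All libraries had a basal epithelial profile. Krt5, a basal keratin, took 1.13% to 1.76% of counts. Krt5 lies outside the naming rule and was chosen after its values were seen. Of the other cell types listed, the transcripts with the highest mean were Mgp (fibroblast and muscle, 31 CPM), Cd68 (immune, 19.2 CPM), Egfl7 (endothelial, 4.55 CPM), Sox2 (neuroendocrine, 35 CPM) and Spint3 (seminal vesicle, 0.165 CPM). The 3 libraries of replicate number 1 had less Gapdh, a glycolytic enzyme transcript, at 2688.3 to 3650.6 CPM, than the other 11, at 4861.8 to 8096.9 CPM.

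Ar, the gene cut by sgAR (chromosome X, 98148769 to 98323215 of mm10), was lower in every sgAR library than in any sgNT library. It measured 97.8 ± 2.27 CPM in sgNT Control and 37.7 ± 7.44 CPM in sgAR Control, and 103 ± 2.73 CPM in sgNT SPOPmut and 29.0 ± 4.54 CPM in sgAR SPOPmut. The guide cuts exon 2 (98251686 to 98251837) and counts cover the whole transcript, so the level checks the guide labels without measuring the edited share or the protein. Fkbp5, a cochaperone gene induced by androgen and glucocorticoid receptors (chromosome 17, 28399094 to 28517527), went the same way: 142 ± 56.7 and 19.4 ± 10.8 CPM in Control, and 174 ± 25.3 and 28.5 ± 7.83 CPM in SPOPmut, with sgNT and sgAR. Tmprss2, another gene with known androgen control, measured 23.5 ± 3.22, 31.8 ± 10.3, 34.7 ± 5.16 and 36.2 ± 6.46 CPM in sgNT Control, sgAR Control, sgNT SPOPmut and sgAR SPOPmut respectively. It was not called in any comparison. Spop (chromosome 11, 95414080 to 95493406) measured 185 ± 28.3, 141 ± 15.8, 186 ± 12.9 and 188 ± 12.3 CPM in the same order. Its total level does not check the genotype labels, since a mutated transcript may be counted as Spop or not at all. Nkx3-1 had 1 count in total, and Pbsn had 0 counts in all 14 libraries, which allows up to 0.19 CPM in the smallest.

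**Figure D1:**
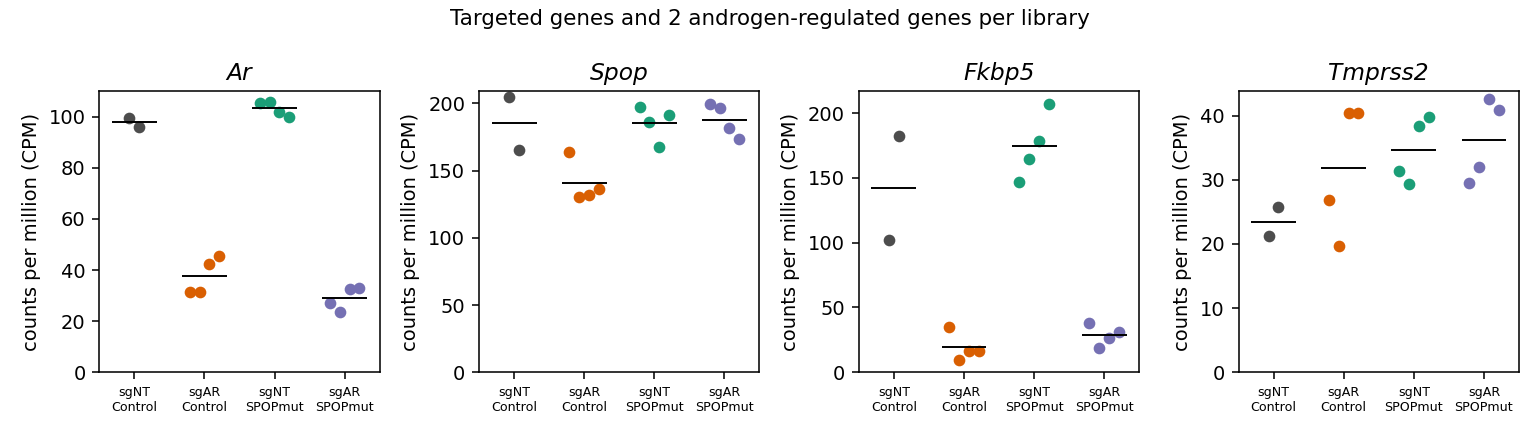
CPM (y axis, linear from 0) of Ar, Spop, Fkbp5 and Tmprss2 in each library (points) with the group mean (line), for the 4 groups on the x axis. Ar sits between 23.4 and 45.7 CPM in the 8 sgAR libraries and between 96.2 and 105.8 CPM in the 6 sgNT libraries.

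AR targeting in Control organoids asked what the androgen receptor maintains in the absence of SPOP mutation. Igfbp2, an insulin-like growth factor binding protein (chromosome 1, 72824503 to 72852474), fell from 47.1 ± 20 to 0.379 ± 0.206 CPM, and the quinone reductase Nqo1 from 74.0 ± 12.4 to 2.15 ± 0.925 CPM. The potassium channel gene Kcnj15 fell from 190 ± 16.5 to 9.74 ± 4.50 CPM, and glutamine synthetase, Glul, from 51.0 ± 19.7 to 4.01 ± 1.91 CPM. Luminal keratins rose at the same time. Krt8 went from 1.06 ± 0.259 to 22.6 ± 7.70 CPM, Krt19 from 17.6 ± 5.59 to 228 ± 78.4 CPM and Krt7 from 5.34 ± 1.26 to 57.4 ± 23.9 CPM. The matrix protein gene Mgp, also a fibroblast marker, went from 3 counts in each sgNT Control library (0.172 CPM) to 92.2 ± 74.3 CPM. The complement protease Masp1 went from 3 counts in each to 29.4 ± 15.4 CPM.

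Among the other large changes, the membrane-associated Basp1 (log2 fold change 5.64, SE 0.73) and the Rho regulator Arhgdib (5.29, SE 0.44) rose. Stc2, a secreted stress-responsive glycoprotein, had 1 to 4 counts per sgNT Control library and 15.9 ± 12.4 CPM in sgAR Control (adjusted p = 0.00401, and 0.0705 without sgNT Control replicate 3). Counts assigned to Pcdhgc3, which shares sequence with its protocadherin cluster, rose by 5.86 (SE 0.43). Gjb2, which encodes connexin 26, fell by 3.12 on the log2 scale (SE 0.63, adjusted p = 0.00699); its call was lost without sgNT Control replicate 2 (0.0673).

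Luminal markers rose as a list, with 9 of 20 tested members up and 0 down, and 11 up and 2 down adjusted over the list alone (adjusted p = 8.73e-05; adjusted p = 0.434 with an estimated correlation). EGFR and MAPK feedback genes rose, with 4 of 22 up and 0 down, and 10 up and 1 down adjusted over the list alone (adjusted p = 1.66e-04; 0.434 as adjusted p with an estimated correlation). They included the phosphatase gene Dusp4 (log2 fold change 3.12, SE 0.53), the ephrin receptor gene Epha4 (1.05, SE 0.22) and the ETS factor gene Etv4 (0.99, SE 0.21). Epha4 and Etv4 lost their calls without sgNT Control replicate 2 (adjusted p = 0.0919 and 0.0522) or replicate 3 (0.0833 and 0.13). Cholesterol and fatty acid synthesis genes rose as a list on 2 of 35 called members, both also called over the list alone (adjusted p = 0.0213; adjusted p = 0.891 with an estimated correlation, 0.0865 with the replicate block and 0.31 by fry), among them the LDL receptor gene Ldlr, from 66.8 ± 15.7 to 241 ± 37.1 CPM. The rise of immune cell markers (adjusted p = 0.012; adjusted p = 0.231 with an estimated correlation) rested on 1 of 5 tested members, both over all genes and adjusted over the list alone. It was the lysozyme gene Lyz2, with 106 to 164 counts in each sgAR Control library and 0 counts in all 10 others.

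The androgen response list was not called (adjusted p = 0.616). Of 54 tested members, 4 rose and 7 fell, and 4 rose and 9 fell adjusted over the list alone, with a mean of 0.15 and a test direction of down. The metalloreductase Steap4 fell from 17.7 ± 8.26 to 0.546 ± 0.340 CPM, while Krt8 and Krt19, which are members too, rose. Ar itself, the gene cut by sgAR, is also a member, so its fall enters the list results by design. The glucocorticoid response list was not called either (0 up and 5 down of 20, also adjusted over the list alone; adjusted p = 0.0653), but was called down with the replicate block (0.0408) and by fry (0.0256). Its members Zbtb16, a zinc finger regulator, and Lcn2, a secreted siderophore-binding protein, went from 1.56 ± 0.360 and 4.45 ± 1.85 CPM to 0 to 1 and 0 to 2 counts per sgAR library. NF-kB and inflammatory genes gave 2 up and 5 down of 25, and 3 up and 6 down adjusted over the list alone (adjusted p = 0.237; called down with the replicate block, 0.0319). The chemokine Cxcl2 (-2.99, SE 0.48) and the cytokine Csf3 (-2.43, SE 0.41) fell. Basal markers gave 2 up and 1 down of 28, and 2 up and 2 down adjusted over the list alone (adjusted p = 0.581, median -0.06, mean 0.04). The basal master regulator Trp63 was lower (-0.51, SE 0.12, adjusted p = 0.02), a call lost without sgNT Control replicate 2 (0.134) or 3 (0.0786) and with chromosome shifts removed (-0.41, 0.0628). Squamous differentiation genes gave 4 up and 2 down of 30, and 5 up and 2 down adjusted over the list alone (adjusted p = 0.616), with the cornified envelope gene Ivl up (1.60, SE 0.27).

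In all, 1211 of 14204 genes were called, 677 up and 534 down (824 up and 966 down with limma-voom, which turned the majority). The count rested on the sgNT Control pair: it was 641 without replicate 2 and 434 without replicate 3 of that group, and 1890 without sgAR Control replicate 2. Fitted from these 6 libraries alone, 300 genes were called and the calls of Gjb2, Dusp4, Epha4, Etv4, Csf3, Trp63 and Ivl were lost (adjusted p from 0.0503 to 0.0978) with log2 fold changes of -3.11, 3.13, 1.06, 1.00, -2.43, -0.50 and 1.61. Spop was not called (-0.40, SE 0.12, adjusted p = 0.0657). It was called without sgAR Control replicate 1 (0.0252) and with the DESeq2 Wald test (0.0253) or limma-voom (0.0247). Genes of chromosome 11, where Spop lies, had a median log2 fold change of -0.28 in this comparison. The Spop values given here are not corrected for that shift.

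AR targeting in SPOPmut organoids asked the same question in the mutant background. Zbtb16 went from 3.01 ± 0.922 CPM to 0 to 1 counts per library, Fkbp5 fell by 2.61 on the log2 scale (SE 0.34), and Igfbp2 fell from 22.5 ± 4.91 to 0.836 ± 0.0905 CPM. The bile acid receptor gene Nr1h4 (chromosome 10, 89454234 to 89533585) went from 21.5 ± 3.78 CPM to 0 to 2 counts per library. Pdpn, which encodes podoplanin, went from 0 to 1 counts per library to 17.7 ± 2.84 CPM, and the galectin Lgals7 from 25.1 ± 7.79 to 304 ± 87.5 CPM. The keratin Krt13 went from 175 ± 35.9 to 1230 ± 339 CPM and fibulin-2, Fbln2, from 3.04 ± 1.26 to 102 ± 6.49 CPM.

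Further large rises were the GABA receptor subunit Gabrp (0.153 ± 0.123 to 21.5 ± 4.27 CPM), the zinc transporter Slc39a4 (log2 fold change 5.82, SE 0.46), Arhgdib (5.78, SE 0.34), the Rac regulator Chn2 (5.74, SE 0.41) and the R-spondin receptor Lgr6 (5.46, SE 0.68). Further large falls were the keratin Krt90 (-6.47, SE 0.72), ceruloplasmin, Cp (-5.03, SE 0.61), and the channel-like gene Tmc4 (-3.61, SE 0.22). The protease inhibitor Spink12 went from 27.6 ± 9.48 to 1.70 ± 1.07 CPM. Pdpn, Lgals7, Krt13, Gabrp, Slc39a4 and Lgr6 were low in sgNT SPOPmut alone, by non-overlapping libraries and a log2 gap of at least 2. So were Notum, Tnfrsf19, Calml3 and Krt17, named below. Nr1h4, Krt90 and Spink12 were high there alone. Krt13, for example, averaged 1460 CPM in sgNT Control. For these genes AR targeting cannot be told apart from drift of the sgNT SPOPmut culture.

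Wnt target genes rose, with 6 of 19 up and 0 down, and 9 up and 1 down adjusted over the list alone (adjusted p = 7.52e-04; adjusted p = 0.168 with an estimated correlation). Besides Lgr6 they included Notum, a secreted Wnt deacylase (2.07, SE 0.28), and Tnfrsf19, which went from 0 to 1 counts to 4.66 ± 1.15 CPM. Lgr6 and Notum averaged 0.549 and 3.16 CPM in sgNT SPOPmut and 24.8 and 13.3 CPM in sgAR SPOPmut. They averaged 23.4 and 13.8 CPM in sgNT Control, so their rise brought them to about that level. TGF-beta and EMT genes rose with 6 of 22 up and 0 down, and 9 up and 0 down adjusted over the list alone (adjusted p = 3.15e-04; adjusted p = 0.459 with an estimated correlation), among them the ligand Tgfb2 (2.36, SE 0.29) and the matrix proteases Mmp9 (3.09, SE 0.40) and Mmp2 (2.60, SE 0.45). NF-kB and inflammatory genes rose with 6 of 25 up and 1 down, and 7 up and 1 down adjusted over the list alone (adjusted p = 1.55e-04; adjusted p = 0.722 with an estimated correlation). Birc3, an inhibitor of apoptosis, rose by 3.68 (SE 0.30), the adhesion molecule Icam1 by 2.13 (SE 0.28) and Csf3 by 2.35 (SE 0.37). Squamous differentiation genes rose with 6 of 30 up and 0 down, and 10 up and 0 down adjusted over the list alone (adjusted p = 0.00114; adjusted p = 0.949 with an estimated correlation and 0.194 by fry), with Calml3 (3.89, SE 0.63) and Ivl (1.32, SE 0.21) beside Krt13.

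Glucocorticoid response genes fell with 0 of 20 up and 6 down, and 0 up and 8 down adjusted over the list alone (adjusted p = 0.0402; adjusted p = 0.722 with an estimated correlation). With the replicate block the list was not called (0.0809). Cebpd, a transcription factor gene of this list, fell by 1.20 (SE 0.23). The androgen response list was not called (adjusted p = 0.293), with 3 of 54 up and 9 down, and 4 up and 12 down adjusted over the list alone; fry called it down (0.0318). Abhd2, a lipase, fell by 1.07 (SE 0.13). Here too the list includes the targeted gene Ar, whose fall enters the list results and the fry call by design. Luminal markers gave 2 up and 3 down of 20, and 3 up and 6 down adjusted over the list alone (adjusted p = 0.876). Cd24a rose by 0.93 (SE 0.10) and Krt7 fell by 1.42 (SE 0.25). Basal markers gave 4 up and 1 down of 28, and 4 up and 3 down adjusted over the list alone (adjusted p = 0.9, median -0.06, mean 0.52; called up by fry, 0.0318), with Krt17 up by 3.07 (SE 0.44). Glycolysis and hypoxia genes (1 up and 0 down of 28; 0 and 0 adjusted over the list alone) were not called (adjusted p = 0.0625) and were called up with the replicate block (0.0333). In all, 1505 genes were called, 870 up and 635 down. Limma-voom called 2829.

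The genes AR targeting changed overlapped between the genotypes, in comparisons that share no library. Fkbp5, Igfbp2, Kcnj15, Zbtb16 and Lcn2 were lower with sgAR in both, and Arhgdib, Fbln2, Tnfrsf19, Cd24a and Ivl were higher in both. Of the genes called in both, 228 rose in both (41.5 expected by chance, Fisher's exact p = 1.29e-113) and 125 fell in both (23.9 expected, p = 1.15e-56). Another 74 went opposite ways (63 expected). Fisher's test takes genes as independent, which they are not. Same-numbered libraries of both comparisons also correlated, so these p values can be too small. The 677 genes that rose in Control had a median log2 fold change of 1.70 there and 0.40 in SPOPmut, and 72.4% had the same sign. For the 534 that fell the medians were -0.78 and -0.12, and 65.5% had the same sign. In reverse, the 870 genes that rose in SPOPmut had medians of 1.40 there and 0.40 in Control (72.1% of the same sign). For the 635 that fell in SPOPmut these were -0.84 and -0.14 (63.5%). Genes chosen by a call have larger fitted effects where they were chosen. These medians therefore do not compare the strength of AR targeting between the genotypes. Across all 14204 genes, which are not independent replicates, the correlation of the effects was 0.294 (Pearson) and 0.174 (Spearman). The 353 genes shared in direction became 228 without sgNT Control replicate 2, 152 without replicate 3 and 554 with limma-voom.

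SPOP mutation with sgNT compared SPOPmut with Control organoids in which the androgen receptor gene was not targeted. Nr1h4 was at 0.224 ± 0.149 CPM in Control and 21.5 ± 3.78 CPM in SPOPmut, and Spink12 went from 1 count in each Control library to 27.6 ± 9.48 CPM. Pdpn fell from 19.8 ± 0.107 CPM to 0 to 1 counts per library. The tripartite motif gene Trim35 (chromosome 14, 66297031 to 66311424) fell from 31.8 ± 4.42 to 0.186 ± 0.129 CPM. Trp63 was at 771 ± 32.8 and 356 ± 21.6 CPM, and Lgals7 at 448 ± 10.3 and 25.1 ± 7.79 CPM in Control and SPOPmut. Krt19 rose from 17.6 ± 5.59 to 379 ± 98.3 CPM and Krt7 from 5.34 ± 1.26 to 66.5 ± 14.7 CPM.

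Other large rises were the zinc finger gene Zfp111 (log2 fold change 5.23, SE 0.25), Apobr, a lipoprotein receptor gene (4.82, SE 0.31), the ceramidase Acer2 (4.53, SE 0.24) and the counts assigned to Pcdhgc3 (4.80, SE 0.41). Other large falls were Gjb2 (-5.78, SE 0.68), Glul (-3.79, SE 0.43), Plxdc2 (-3.66, SE 0.33) and the microsomal glutathione transferase Mgst1 (-3.35, SE 0.30).

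Cholesterol and fatty acid synthesis genes rose, with 7 of 35 up and 0 down, and 11 up and 0 down adjusted over the list alone (adjusted p = 7.17e-06; adjusted p = 0.886 with an estimated correlation and 0.0728 by fry). Ldlr rose from 66.8 ± 15.7 to 239 ± 27.6 CPM, the PCSK9 gene Pcsk9 by 1.91 (SE 0.50) and squalene epoxidase, Sqle, by 0.51 (SE 0.12). Sqle, on chromosome 15, lost its call with chromosome shifts removed (0.14, adjusted p = 0.589) and without sgNT Control replicate 2 (0.198). Pcsk9 lost it without sgNT Control replicate 2 (0.232) or sgNT SPOPmut replicate 3 (0.0506) or 4 (0.0502), and without the libraries of replicate number 1 (0.0555). Luminal markers rose with 5 of 20 up and 0 down, and 5 and 0 adjusted over the list alone (adjusted p = 0.0279; adjusted p = 0.886 with an estimated correlation and 0.0684 with the replicate block), the tetraspanin Tspan8 among them (2.56, SE 0.48; adjusted p = 0.0736 without sgNT Control replicate 2). EGFR and MAPK feedback genes rose with 2 of 22 up and 0 down, and 5 up and 0 down adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.886 with an estimated correlation). The 2 were Dusp4 (1.75, SE 0.50) and Epha4 (0.77, SE 0.22). Both calls were lost without sgNT Control replicate 2 (0.235 and 0.24) or 3 (0.146 and 0.141) and without sgNT SPOPmut replicate 3 (0.0642 and 0.0745) or 4 (0.0705 and 0.0874), and that of Dusp4 without sgNT SPOPmut replicate 1 (0.0822). Dusp4 also lost it with limma-voom (0.0909) and without the libraries of replicate number 1 (0.105), and Epha4 with chromosome shifts removed (log2 fold change 0.61, adjusted p = 0.148).

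NF-kB and inflammatory genes fell with 0 of 25 up and 4 down, and 0 up and 4 down adjusted over the list alone (adjusted p = 0.038; adjusted p = 0.886 with an estimated correlation and 0.191 by fry). Csf3 fell by 2.56 (SE 0.41), Icam1 by 1.28 (SE 0.32) and the acute phase gene Saa3 by 1.99 (SE 0.50). Without sgNT Control replicate 2 the calls of Icam1 (0.255) and Saa3 (0.205) were lost, as was that of Icam1 without sgNT SPOPmut replicate 1 (0.0502) and that of Saa3 without sgNT SPOPmut replicate 3 (0.0543) or 4 (0.0564). The androgen response list gave 5 up and 7 down of 54, and 5 and 7 adjusted over the list alone (adjusted p = 0.991). Basal markers gave 1 up and 5 down of 28, and 2 up and 6 down adjusted over the list alone (adjusted p = 0.635, median 0.14, mean -0.45). Squamous genes gave 1 up and 3 down of 30, and 1 and 3 adjusted over the list alone (adjusted p = 0.374). Krt13 fell by 3.07 (SE 0.39). Of reported SPOP substrates and regulators, 2 of 34 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.635). These are transcript levels and do not show whether the proteins changed. Spop and Ar are on that list. The AR coactivator and SPOP substrate gene Ncoa3, on chromosome 2, rose by 0.70 (SE 0.13), a call lost with chromosome shifts removed (0.36, adjusted p = 0.101) and without sgNT Control replicate 2 (0.0541). In all, 1531 genes were called, 763 up and 768 down. The count was 530 without sgNT Control replicate 2, 768 without replicate 3, 1001 and 987 without sgNT SPOPmut replicates 3 and 4, and 925 with chromosome shifts removed. Ar, Spop and Fkbp5 were not called (0.08, 0.00 and 0.30; adjusted p = 0.811, 0.988 and 0.686).

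**Figure D2:**
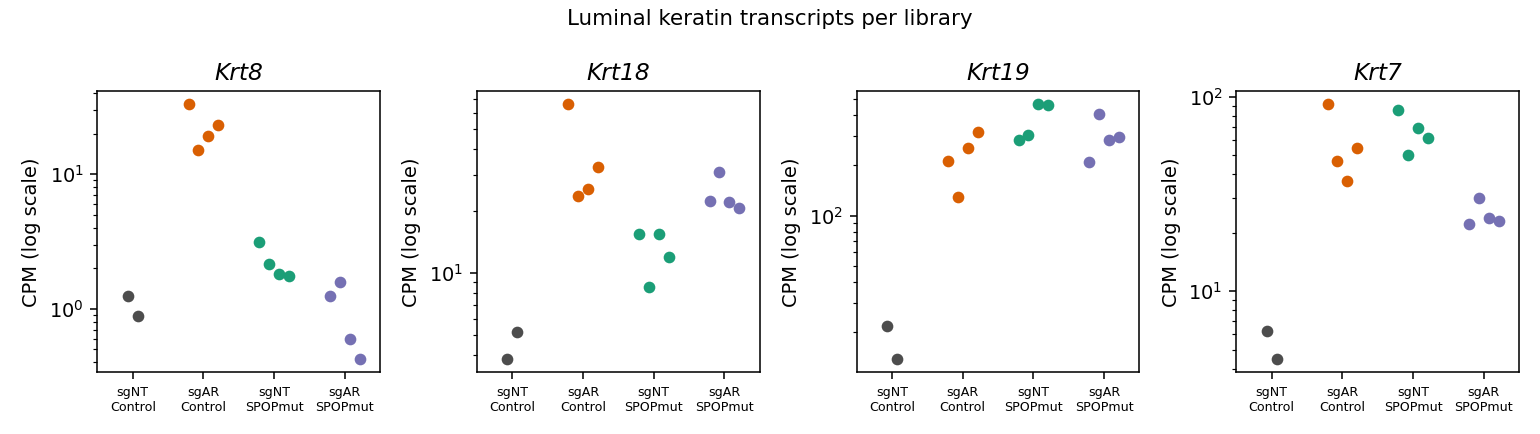
CPM (y axis, log scale) of Krt8, Krt18, Krt19 and Krt7 in each library (points), for the 4 groups on the x axis; Krt18 was added after its values were seen. Krt8 lies near 1 CPM in sgNT Control and sgAR SPOPmut and averages 22.6 CPM in sgAR Control, while Krt19 averages 228 to 379 CPM in every group but sgNT Control.

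SPOP mutation with sgAR asked which effects of the mutation are present after AR targeting. Nqo1 was at 2.15 ± 0.925 CPM in Control and 49.8 ± 8.83 CPM in SPOPmut, and the transporter Abcc3 at 1.78 ± 1.08 and 39.4 ± 4.44 CPM. The glutathione transferase Gstm2 rose from 8.42 ± 3.23 to 86.2 ± 10.6 CPM. Krt8 fell from 22.6 ± 7.70 to 0.960 ± 0.547 CPM, and the membrane protein gene Mal (chromosome 2, 127633226 to 127656695) from 44.0 ± 18.8 to 0.472 ± 0.0972 CPM. Lyz2 went from 7.44 ± 0.638 CPM to 0 counts in all 4 SPOPmut libraries.

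Other large rises were Chn2 (log2 fold change 3.75, SE 0.36), the retinol dehydrogenase Rdh12 (3.01, SE 0.36) and the glycosyltransferase Galnt6 (2.80, SE 0.22). Other large falls were the tight junction gene Cldn1 (-4.76, SE 0.60), Plxdc2 (-4.59, SE 0.33), the retinoic acid binding protein gene Crabp2 (-4.24, SE 0.36) and Cp (-4.24, SE 0.60).

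Fry called none of the 5 lists called here (0.105 to 0.468). NF-kB and inflammatory genes rose with 5 of 25 up and 1 down, and 9 up and 1 down adjusted over the list alone (adjusted p = 0.00422; adjusted p = 0.954 with an estimated correlation), including complement C3 (1.30, SE 0.12), Csf3 (2.22, SE 0.36) and Cxcl2 (2.39, SE 0.43). Cell cycle genes rose as a list with a median of 0.30 (adjusted p = 0.00204; adjusted p = 0.954 with an estimated correlation), although 0 of 40 members were called, over all genes or adjusted over the list alone. Homologous recombination genes rose (adjusted p = 0.00574; adjusted p = 0.954 with an estimated correlation) with 1 of 31 called, over all genes and adjusted over the list alone: Rbbp8, a DNA end resection factor (0.53, SE 0.12). Its call was lost without sgAR SPOPmut replicate 3 (0.0539) or 4 (0.0502), with only these groups fitted (0.062, log2 fold change 0.52) and with chromosome shifts removed (0.0831, log2 fold change 0.42). Cholesterol and fatty acid synthesis genes rose with 3 of 35 up and 0 down, and 3 and 0 adjusted over the list alone (adjusted p = 0.0419; adjusted p = 0.954 with an estimated correlation). These were the sterol isomerase Ebp (1.08, SE 0.15), squalene synthase, Fdft1 (0.59, SE 0.10), and Sqle (0.52, SE 0.09).

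Luminal markers fell with 1 of 20 up and 2 down, and 1 up and 3 down adjusted over the list alone (adjusted p = 0.0419; adjusted p = 0.954 with an estimated correlation). Krt7 fell by 1.21 (SE 0.25) beside Krt8, and the epithelial factor Ehf rose by 0.71 (SE 0.20). The Ehf call (adjusted p = 0.0461) was lost without sgAR Control replicate 1 or 2 or any of the 4 sgAR SPOPmut libraries (0.0502 to 0.14), with only these groups fitted (0.114), with chromosome shifts removed (0.101) and without the libraries of replicate number 1 (0.0881). Its log2 fold changes in these 3 fits were 0.70, 0.62 and 0.75. The androgen response list gave 0 up and 6 down of 54, and 2 up and 8 down adjusted over the list alone (adjusted p = 0.373). Immediate early genes gave 0 called of 26, also adjusted over the list alone (adjusted p = 0.239), and were called down with the replicate block (0.0274). Trp63 was lower (-0.44, SE 0.10, adjusted p = 0.0158), a call lost without sgAR SPOPmut replicate 4 (0.0552) and with only these groups fitted (-0.46, 0.0647). Spop was higher (0.42, SE 0.10, adjusted p = 0.0229). That call was lost without sgAR Control replicate 3 or 4 or sgAR SPOPmut replicate 1, 2 or 3 (0.0514 to 0.0791), with no filter (0.0532), with only these groups (0.0581) and with chromosome shifts removed (0.0892). Its log2 fold changes in the last 3 fits were 0.41, 0.41 and 0.33. Ar (-0.38, adjusted p = 0.114) and Fkbp5 (0.55, adjusted p = 0.345) were not called; Ar was without sgAR Control replicate 2 and Fkbp5 without replicate 1, and both were with limma-voom (0.00585 and 0.0221).

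In all, 1178 genes were called, 591 up and 587 down, and 2082 with the replicate block. The count was 773 without sgAR SPOPmut replicate 3, 686 with only these groups fitted and 3513 with limma-voom. The SPOP effects overlapped between the guides, in comparisons that share no library. Of the genes called in both, 153 rose in both and 140 fell in both (31.7 expected each, Fisher's exact p = 6.23e-65 and 5.38e-54). Another 70 went opposite ways (63.5 expected). As for the AR effects, these p values take genes as independent and can be too small. Plxdc2 and Trp63 fell and Sqle rose in both. The Sqle call with sgNT was lost with chromosome shifts removed (0.14, adjusted p = 0.589). The 763 genes that rose with sgNT had medians of 1.02 there and 0.18 with sgAR, and 68.2% had the same sign. For the 768 that fell the medians were -0.95 and -0.16, and 65% had the same sign. In reverse, the 591 genes that rose with sgAR had medians of 0.90 there and 0.28 with sgNT (69% of the same sign). For the 587 that fell with sgAR these were -0.87 and -0.23 (67.3%). Here too the smaller second median follows from choosing genes by their call, and it does not compare the strength of the SPOP effects. Across genes, which are not independent replicates, the correlation was 0.157 (Pearson) and 0.18 (Spearman). The 293 genes shared in direction became 490 with the replicate block, 131 and 189 without sgNT Control replicates 2 and 3, 195 without sgAR SPOPmut replicate 3, 462 with the DESeq2 Wald test and 640 with limma-voom. With chromosome shifts removed 205 were shared. Genes of chromosomes 4, 8 and 15 had median shifts of the same sign with sgNT and sgAR (-0.29 and -0.15, -0.18 and -0.18, 0.37 and 0.18). Those of chromosomes 1 and 11 had opposite signs (0.17 and -0.1, -0.17 and 0.08). The overlap can thus include genes that moved with their chromosome.

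The interaction asked whether SPOP mutation acts differently once AR is targeted, and equally whether AR targeting acts differently in mutant organoids. Nqo1 fell with AR targeting in Control and was at 20.1 ± 2.19 CPM with sgNT and 49.8 ± 8.83 CPM with sgAR in SPOPmut, an interaction of 6.41 on the log2 scale (SE 0.37). Krt8 (-5.63, SE 0.63), Krt7 (-4.85, SE 0.44) and Krt19 (-4.04, SE 0.48) had negative interactions. They rose with AR targeting in Control, and in SPOPmut Krt7 fell while Krt8 (2.22 ± 0.651 and 0.960 ± 0.547 CPM) and Krt19 (379 ± 98.3 and 299 ± 80.2 CPM) were not called. Lgals7 (4.72, SE 0.45) and Gjb2 (4.67, SE 0.84) had positive interactions and their lowest means in sgNT SPOPmut. Glul (6.37, SE 0.58) was low in both sgAR Control and sgNT SPOPmut (4.01 ± 1.91 and 3.70 ± 1.47 CPM). Trim35 had 1 to 6 counts per sgNT SPOPmut library and 31.8 ± 4.42, 17.3 ± 6.10 and 12.5 ± 2.32 CPM in sgNT Control, sgAR Control and sgAR SPOPmut (adjusted p = 2.00e-06). Pdpn, at 0 to 1 counts in sgNT SPOPmut, was at 19.8 ± 0.107, 9.31 ± 5.96 and 17.7 ± 2.84 CPM in sgNT Control, sgAR Control and sgAR SPOPmut (adjusted p = 2.03e-06).

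Negative interactions were also large for Mal (-7.40, SE 0.53), Crabp2 (-5.52, SE 0.59), the zinc finger regulator Sall3 (-5.30, SE 0.37) and the counts of Pcdhgc3 (-5.20, SE 0.47). Masp1 was low in sgNT Control alone (adjusted p = 4.49e-04), at 3 counts in each library against 29.4 ± 15.4, 13.9 ± 8.53 and 12.2 ± 5.43 CPM in sgAR Control, sgNT SPOPmut and sgAR SPOPmut. Krt90 (-5.72, SE 1.05, adjusted p = 0.00551) varied in sgNT SPOPmut (35.2 ± 31.1 CPM) and lost its call without sgNT Control replicate 3 (0.0518).

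As lists, NF-kB and inflammatory genes had a positive interaction, with 5 of 25 up and 0 down, and 10 and 0 adjusted over the list alone (adjusted p = 5.93e-05; adjusted p = 0.757 with an estimated correlation). Csf3 (4.78, SE 0.55), Cxcl2 (3.62, SE 0.62) and C3 (1.25, SE 0.19) were among them. Luminal markers had a negative interaction, with 0 up and 6 down of 20, and 0 and 8 adjusted over the list alone (adjusted p = 2.5e-04; adjusted p = 0.757 with an estimated correlation). EGFR and MAPK feedback genes did too, with 0 up and 2 down of 22, and 0 and 3 adjusted over the list alone (adjusted p = 8.62e-04; adjusted p = 0.757 with an estimated correlation). The 2 were Spry1, a receptor tyrosine kinase antagonist (-2.15, SE 0.47), whose call was lost without sgNT Control replicate 3 (0.11), and Dusp4 (-2.37, SE 0.61, adjusted p = 0.0369). The Dusp4 call was lost without any of 11 libraries (0.0546 to 0.16): both of sgNT Control, sgAR Control replicates 1, 3 and 4, sgNT SPOPmut replicates 1, 3 and 4, and sgAR SPOPmut replicates 1, 2 and 3. It was also lost without the libraries of replicate number 1 (0.13). Cholesterol and fatty acid synthesis genes had a negative interaction (adjusted p = 0.0364; adjusted p = 0.919 with an estimated correlation) with 1 up and 1 down of 35, also adjusted over the list alone, the latter being Ldlr (-1.80, SE 0.23). With the replicate block and by fry that list was not called (0.0535 and 0.482).

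Ar, Spop, Fkbp5 and Tmprss2 showed no called interaction (adjusted p = 0.266, 0.173, 0.825 and 0.593), nor did the androgen response list (2 up and 5 down of 54, and 5 and 5 adjusted over the list alone; adjusted p = 0.554). In all, 773 genes had a called interaction, 400 positive and 373 negative. The count was 423 and 392 without sgNT Control replicates 2 and 3, 1206 without sgAR Control replicate 2, 1236 with the DESeq2 Wald test and 1535 with limma-voom.

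Whole chromosomes were shifted between groups, as medians over their genes with a mean log2 CPM above 3 show. For SPOP mutation with sgNT, genes of chromosome 2 had a median log2 fold change of 0.37 (160 called up and 25 down of 1160 tested), those of chromosome 15 of 0.37 (85 and 14 of 545), those of chromosome 18 of 0.35 (50 and 4 of 364) and those of chromosome 14 of -0.34 (12 and 77 of 490). For AR targeting in Control, chromosome 14 had a median of -0.36 (18 up and 76 down). Chromosomes 11 and 13 had medians of -0.28 (30 up and 109 down) and -0.27 (17 and 43) there. For SPOP mutation with sgNT, chromosome 4 had a median of -0.29 (16 up and 111 down). The largest median shifts for AR targeting in SPOPmut and SPOP mutation with sgAR were 0.19 in size. The libraries of the compared groups were fully separated on 15, 6, 17 and 11 of 20 chromosomes. These are for AR targeting in Control and in SPOPmut and SPOP mutation with sgNT and with sgAR. For exchangeable libraries chance gives 13.33%, 2.86%, 13.33% and 2.86%. Same-numbered libraries correlated in the comparisons with 2.86%, so that value is only a guide. Among the genes named, Mal, Plxdc2, Ehf, Gata3, Mmp9, Lcn2 and Ncoa3 lie on chromosome 2, and Trim35, Gjb2, Tnfrsf19 and Fdft1 on 14. Krt5, Krt7, Krt8, Krt18, Krt90, Basp1, Slc39a4, Galnt6 and Sqle lie on 15, and Spink12, Sall3, Rbbp8 and Pcdhgc3 on 18.

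**Figure D3:**
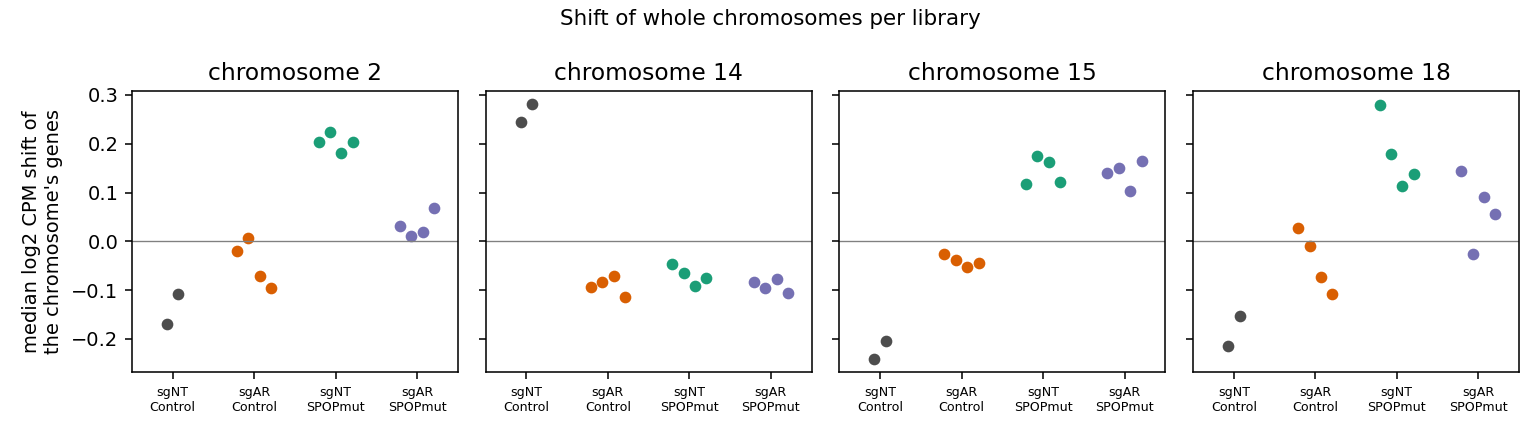
Median difference of the log2 CPM of a chromosome's genes from the mean of the 4 group means (y axis, genes with a mean log2 CPM above 3) in each library (points), for chromosomes 2, 14, 15 and 18, with the 4 groups on the x axis. On chromosome 14 the 2 sgNT Control libraries lie at 0.244 and 0.281 and the 12 others between -0.113 and -0.046.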

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

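The tests of admixed luminal cells, of AR loss in either genotype and of the 2 sgNT Control libraries behind the chromosome shifts were chosen after the results they measure were seen, as was Krt18.

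Many genes were set apart in a single group. By non-overlapping libraries and a gap of at least 2 on the log2 scale, 259 genes had 1 group apart (85 in sgNT Control, 43 in sgAR Control, 95 in sgNT SPOPmut and 36 in sgAR SPOPmut). By the same measure 98 followed a factor, 72 the guide in both genotypes and 26 the genotype with both guides, so the guide alone had more genes than sgAR Control or sgAR SPOPmut. No chromosome was enriched at least 3-fold for the 259 genes with an adjusted Fisher p below 0.05. The lowest p among such enrichments was 0.402, for 6 genes on chromosome 15 in sgAR Control. This cannot decide on a gain or loss of a chromosome. The chromosome shifts measured here were at most 0.37 in size, too small to give a gap of 2. The small sgNT Control group as the source of most of these genes is argued against, as it held 32.8% of the 259. For its own 85 genes this share cannot decide, since fewer libraries part from all others more easily. Drift between separately kept organoid lines cannot be told apart from a joint effect of guide and genotype, since the labels do not say how many lines a group holds and the 259 genes go with the groups either way.

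Luminal keratins were lowest in sgNT Control for Krt19, Krt7 and Krt18, which were higher in all 3 other groups, while Krt8 stood out in sgAR Control (22.6 CPM, against 0.96 to 2.22 in the other groups). Chance in 1 of the 2 sgNT Control libraries alone is argued against for Krt18. It was called in AR targeting in Control without either of them (highest adjusted p = 0.0201, log2 fold changes of 2.84 and 3.25). Each of these fits keeps 1 sgNT Control library, which is assumed to vary like the other groups. Krt18 was also chosen after its values were seen. A low level shared by both libraries by chance therefore stays open. A rise with AR loss in either genotype is argued against for Krt7, Krt8 and Krt19. Their log2 fold changes in SPOPmut of -1.42 (SE 0.25), -1.22 (SE 0.38) and -0.34 (SE 0.27) differed from those in Control by called interactions (highest adjusted p of the 3, 1.88e-04). Such a rise stays open for Krt18 (0.90, SE 0.30, adjusted p = 0.0775). Krt18 had a called negative interaction as well (-2.14, SE 0.51, adjusted p = 0.0251), so its fitted change was smaller in SPOPmut than in Control. Admixed luminal cells stay open: the ratio of added Krt19 to added Krt8 differed at least 9.37-fold in all 16 pairs of sgAR Control and sgNT SPOPmut libraries, but the keratin profile such cells would have in each group is not measured. A change of cell state and a difference between lines were not tested for these genes.

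Whole chromosomes were shifted. A difference in copy number between the cultures would move all parts of a chromosome alike, and for chromosomes 2, 14, 15 and 18 in SPOP mutation with sgNT every part, by position or by expression, moved with the whole by at least 0.31. Bias from GC content or gene length is argued against, since 98.8% of the mean shift of these 4 stayed after its removal (0.36 before and 0.35 after). The 2 sgNT Control libraries as the whole source were weighed in the 2 comparisons without that group. They are argued against for chromosomes 2 and 15, which separated groups of 4 libraries by 0.19 and 0.18. They are not for chromosome 14, with at most 0.03. Chromosome 18 had at most 0.14 and no separation in these comparisons. Its sgNT SPOPmut libraries (shifts of 0.114 to 0.279) all lay above its sgAR Control libraries (-0.108 to 0.028), which argues against that source for chromosome 18 too. A candidate explanation is copy number that differs between the cultures, which the groups cannot part from genotype or guide and for which DNA was not analysed here.

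Effects of SPOP mutation differed between the guides, by the test of the interaction, for 773 genes and for 4 lists: luminal markers (adjusted p = 2.5e-04), cholesterol and fatty acid synthesis (0.0364), NF-kB and inflammatory genes (5.93e-05) and EGFR and MAPK feedback genes (8.62e-04). With an estimated correlation none of the 4 was past the threshold (0.757, and 0.919 for cholesterol), nor was cholesterol with the replicate block (0.0535) or by fry (0.482). Of the 84 genes named, 53 differed. The naming rule took some of them for their called interaction, which raises that share. Over all genes tested it was 773 of 14204. Fitted log2 differences (sgAR minus sgNT) were positive for Pdpn 10.86, Trim35 6.90, Nqo1 6.41, Glul 6.37, Csf3 4.78, Lgals7 4.72 and Gjb2 4.67. At the next sizes came Lgr6 4.65, Slc39a4 4.45, Mmp2 4.27, Abcc3 3.77, Chn2 3.73, Cxcl2 3.62 and Mgst1 3.58. Smaller were Tnfrsf19 3.28, Gabrp 3.17, Krt17 2.67, Krt13 2.28, Igfbp2 2.20, Tgfb2 2.11 and Icam1 1.78. Smallest were Galnt6 1.73, Kcnj15 1.45, C3 1.25, Fdft1 0.75 and Trp63 0.67. They were negative for Masp1 -7.55, Mal -7.40, Nr1h4 -6.92, Spink12 -6.08, Krt90 -5.72, Krt8 -5.63 and Crabp2 -5.52. Next in size were Sall3 -5.30, Pcdhgc3 -5.20, Zfp111 -5.05, Cp -5.03, Apobr -4.97, Krt7 -4.85 and Cldn1 -4.62. Smaller in size were Acer2 -4.61, Krt19 -4.04, Basp1 -3.56, Tspan8 -3.40, Lef1 -3.02, Dusp4 -2.37 and Spry1 -2.15. Last came Tmc4 -2.12, Ldlr -1.80, Cebpd -1.48, Mdm2 -1.20, Gata3 -0.93 and Ncoa3 -0.64. For Pdpn, Nr1h4, Masp1, Spink12, Tnfrsf19, Gabrp and Trim35, which had few counts in some group, these sizes depend on the prior count and are no bounds.

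Libraries far from the other 3 of their group were found in 28 of 255 tests (11%), where chance gives about 13. In 5 of them (Lcn2, Nr1h4, Pdpn, Tnfrsf19 and Zbtb16) 1 or 2 counts stood against 0 in the other 3 libraries, which sets a library apart by construction. Of the other 23, 13 were in libraries of replicate number 1, which had the lowest Gapdh. The total of sgAR Control replicate 4 was 16.2 in units of 1000000 counts, against 18.9 to 19.2 in the rest of its group. Values below are in CPM, with those of the group's other libraries in brackets. sgAR Control replicate 1 had Krt90 at 4.59 (0.941 to 1.27) and Lcn2 at 0.0997 (0). It also had Lgr6 at 82.7 (21.9 to 30.9) and Pdpn at 18.2 (5.49 to 6.95). Further, it had Sall3 at 31.8 (21.1 to 22.8) and Spry1 at 14.8 (7.16 to 7.76). There too, it had Zfp111 at 21.3 (14.4 to 14.9). sgAR Control replicate 2 had Ldlr at 186 (253 to 267) and Lgals7 at 343 (146 to 171). With these came Stc2 at 34.4 (8.48 to 10.4). sgAR SPOPmut replicate 1 had Chn2 at 17.3 (30.7 to 32.6) and Nr1h4 at 0.118 (0). It also had Pcdhgc3 at 71.8 (45.2 to 49.1). sgAR SPOPmut replicate 3 had Cldn1 at 1.37 (0.671 to 0.769) and Fbln2 at 92.7 (105 to 106). sgAR SPOPmut replicate 4 had Zbtb16 at 0.0521 (0). sgNT SPOPmut replicate 1 had Hoxa13 at 8.54 (5.88 to 6.25) and Krt17 at 319 (88.7 to 116). Further, it had Krt90 at 81.8 (18.4 to 20.5) and Masp1 at 26.6 (8.85 to 10.1). There too, it had Spry1 at 9.65 (5.95 to 6.31). sgNT SPOPmut replicate 2 had Apobr at 32.4 (46.6 to 47) and Fbln2 at 4.93 (2.21 to 2.54). With these came Rdh12 at 7.47 (5.3 to 5.51). sgNT SPOPmut replicate 3 had Tnfrsf19 at 0.0445 (0). sgNT SPOPmut replicate 4 had Glul at 5.88 (2.79 to 3.29) and Pdpn at 0.0626 (0).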

How the results depend on the processing

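The removal of chromosome shifts and the fit without the libraries of replicate number 1 were chosen after the data were seen while the others were set beforehand. Of 154 gene results named, 139 past the threshold, and 48 list results, 22 past it, none that was past the threshold in either fit changed direction, and DESeq2 size factors in place of TMM changed no call. Calls were lost for 7 gene results with chromosome shifts removed, for 12 with only the groups compared, for 1 each with limma-voom and no filter, for 4 without the libraries of replicate number 1, and for 13 and 10 without sgNT Control replicates 2 and 3. The replicate block added 1 gene call (Spop in AR targeting in Control) and changed no other gene call. Among lists, all 22 calls were lost with an estimated correlation and 10 with fry, which does not compare a list with other genes. Those lost by fry were luminal markers (0.105), NF-kB (0.105), cell cycle (0.468), homologous recombination (0.452) and cholesterol (0.468) in SPOP mutation with sgAR, cholesterol (0.0728) and NF-kB (0.191) in SPOP mutation with sgNT, squamous genes in AR targeting in SPOPmut (0.194), and cholesterol in AR targeting in Control (0.31) and the interaction (0.482). Among the 48 list results, fry added 5. In AR targeting in Control these were glucocorticoid response (down, 0.0256), Wnt targets (up, 0.00112) and lineage factors (up, 0.0421). In AR targeting in SPOPmut they were androgen response (down, 0.0318) and basal markers (up, 0.0318). Fry calls outside the 48 were not counted, such as prostate secretory genes in AR targeting in Control (up, 0.0386). The block ended 4: cholesterol and fatty acid synthesis in AR targeting in Control (0.0865) and in the interaction (0.0535), glucocorticoid response in AR targeting in SPOPmut (0.0809) and luminal markers in SPOP mutation with sgNT (0.0684). It added 7. In AR targeting in Control these were glucocorticoid response (0.0408), NF-kB (0.0319), cell cycle (0.0112) and homologous recombination (0.00187). The others were glycolysis in AR targeting in SPOPmut (0.0333), immediate early genes in SPOP mutation with sgAR (0.0274) and homologous recombination in the interaction (0.00314).

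Changes of sign, all among results not called in either fit, were as follows. Spop in SPOP mutation with sgNT, at 0.00, became -0.02 with DESeq2 size factors and the Wald test, -0.01 with no filter and with only the groups compared, 0.00 but below 0 with limma-voom, -0.04 with the block and without the libraries of replicate number 1, and -0.18, -0.03 and -0.01 without sgNT Control replicate 3 and sgNT SPOPmut replicates 1 and 4. Ar there became -0.12 with chromosome shifts removed (0.08 before), and Fkbp5 -0.07 without sgNT Control replicate 2 (0.30 before). In AR targeting in SPOPmut, 3 leave-outs gave -0.03 to -0.01 for Spop (0.02 before) and 2 gave -0.03 and -0.01 for Tmprss2 (0.06 before). Tmprss2 in SPOP mutation with sgAR became -0.01 with limma-voom (0.19 before), and the Fkbp5 interaction (0.26 before) -0.19 without sgNT Control replicate 3 and 0.03 in the leave-out with the highest p. With the block the direction of the androgen response list in SPOP mutation with sgNT (0.913) and of glucocorticoid response in the interaction (0.898) turned.

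Numbers of genes called (AR targeting in Control, AR targeting in SPOPmut, SPOP mutation with sgNT, with sgAR, interaction) were 1211, 1505, 1531, 1178 and 773. They stayed within 1.5 times under the alternatives except as follows. With only the groups compared, AR targeting in Control gave 300 and SPOP mutation with sgAR 686. With limma-voom, AR targeting in SPOPmut gave 2829, SPOP mutation with sgAR 3513, the interaction 1535, and the genes shared by the AR effects and by the SPOP effects 554 and 640. The DESeq2 Wald test gave 1236 for the interaction and 462 shared SPOP effects. The block gave 2082 for SPOP mutation with sgAR and 490 shared SPOP effects. Removing chromosome shifts gave 925 for SPOP mutation with sgNT. A minimum absolute log2 fold change of 1, which by construction counts fewer genes, gave 674, 851, 758 and 530 in the first 4 comparisons, 232 shared AR effects and 148 shared SPOP effects. For the other alternatives the cause was not tested.

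Leaving out 1 library gave 434 to 1890 genes for AR targeting in Control, 1087 to 1298 in SPOPmut, 530 to 1299 for SPOP mutation with sgNT, 773 to 1419 with sgAR, 392 to 1206 for the interaction, 152 to 484 shared AR effects and 131 to 373 shared SPOP effects. Where sgNT Control is used, the lowest counts came without a library of that group. With 1 library left, that library is assumed to vary like the other groups. Blocked values of the comparisons with sgNT Control, whose numbers did not qualify as pairs, were 1651 genes for AR targeting and 1943 for SPOP mutation. The block gave 2256 genes for AR targeting in SPOPmut, 1127 for the interaction and 508 shared AR effects. The planned return of the 2 excluded sgNT Control samples could not be run, as they have no column. Without the libraries of replicate number 1 the 5 counts were 1136, 1248, 1381, 913 and 611. The limit of depth is 0.19 CPM for a count of 0, and at 2-fold the simulated recovery was lowest for the interaction, at 24% of 100 genes.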

Other observations

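Of the tests below, the check in separate sgNT libraries was chosen after the result was seen. Prostate lineage transcription factors gave 7 up and 2 down of 27 with AR targeting in Control (12 up and 5 down adjusted over the list alone; adjusted p = 0.143, and 0.0421 by fry) and 3 up and 1 down in SPOPmut (5 and 2 adjusted over the list alone; adjusted p = 0.9). The targeted gene Ar is a member of this list. Gata3, a luminal lineage factor, rose in both (1.55, SE 0.19, and 0.63, SE 0.14), as did the posterior patterning gene Hoxa13 (1.36, SE 0.28, and 1.15, SE 0.21). The Hoxa13 call in Control was lost without sgNT Control replicate 3 (0.133) and with only the groups compared (log2 fold change 1.36, adjusted p = 0.0629). With AR targeting in Control, Wnt target genes gave 5 up and 0 down of 19 (7 up and 3 down adjusted over the list alone; adjusted p = 0.115, and 0.00112 by fry), with Tnfrsf19 (4.58, SE 0.36) and the Wnt effector Lef1 (3.73, SE 0.55) up. For SPOP mutation with sgAR, p53 targets gave 1 up and 2 down of 28, also adjusted over the list alone (adjusted p = 0.648); Mdm2, which encodes the p53 ubiquitin ligase, fell by 1.39 (SE 0.13).

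Other splits of the 8 libraries into 4 and 4 were fitted where both groups had 4. For AR targeting in SPOPmut the real split gave 1773 calls from these libraries alone and the highest of the other splits 9, out of 35 in all. For SPOP mutation with sgAR these were 686 and 2. Same-numbered libraries of these groups were correlated, so only the splits that part all pairs compare with the real one. There are 8, of which 1, the real one, gave as many calls and the highest other gave 0 in both comparisons; 8 are too few for a share under 0.05. The remaining splits keep at least 1 pair of same-numbered libraries together. The comparisons with sgNT Control had too few libraries for this test.

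A hypothesis was that SPOP mutation raises transcripts that depend on AR. The 125 genes that fell with AR targeting in both genotypes had a median log2 fold change of -0.01 for SPOP mutation with sgNT, at percentile 23 of 10000 random lists matched on expression (95% of them from -0.07 to 0.12), with 15 called up and 14 down. The bound set beforehand would have excluded the hypothesis, but it was not applied, because these genes were chosen through the same sgNT libraries, and a high value by chance in sgNT Control both selects a gene and lowers its SPOP effect. A check added after this result chose and measured the genes in separate sgNT libraries, and its outcomes differed: a median of 0.19 for 36 genes (percentile 95.7) and of -0.06 for 51 genes (percentile 15.8). The data therefore leave open whether such a rise exists.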
